A study of Saccharomyces cerevisiae with 121 samples.

How the data were processed

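The series holds 121 sequencing libraries of tRNA 3′ ends from Saccharomyces cerevisiae, in 31 groups of strain and time at 37 °C over 10 strains. Per the labels' protocols, cultures grew in rich medium at 28 °C and were shifted to 37 °C, RNA was taken with hot phenol, and a pre-adenylated linker was ligated to the 3′ ends of total RNA with truncated T4 RNA ligase 2. Reverse transcription from the linker and PCR with a tRNA-specific forward primer followed, per the labels' protocols, in which the text ends partway through the PCR program. The forward primer GGCTCTGCCCGCGCTGG reads the endogenous tRNASer(CGA) and tRNASer(UGA), which the labels describe as inseparable by this method. The primer GCGGGTTCAAATCCCGC was used for 2 strains with altered tRNASer(CGA), and for the U6:A67 variant the authors amplified with the endogenous primer and kept only reads that carried A67, per the labels' protocols.

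The deposited values are raw read counts. Each deposited file lists the distinct reads of 1 library with the number of times each was seen, collapsed by the authors, with the linker already removed. How the authors trimmed, filtered and collapsed reads is not given in the sources used here. The deposited counts are not normalized and had no unit of a feature table, since a count belongs to a read sequence and not to a gene. A read begins with the library's 7 nt barcode and the 17 nt primer. The reads have no molecular identifiers, so PCR copies were counted as reads, and all confidence intervals and detection floors cover counting error only.

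Reads were assigned to the tRNA when they matched barcode, primer and the tRNA body without a mismatch and reached at least position 67, which is 6 bases short of the last body position, 73. The endogenous body from position 54 to 73 is TTCAAATCCTGCTGGTGTCG, that of the U6:A67 variant TTCAAATCCTGCTAGTGTCG. For the other variants the read body runs from position 66 to 73, TGGTGTCG for G51:C63 and TGGTGCCG for the triple variant. The sequence after position 73 is called the 3′ end form. Forms were sorted into CCA, CCACCA, ends short of CCA, a partial second CCA (CCAC or CCACC), CCA followed by A only, CCA with other added bases, and CCACCA with further bases. Forms that begin with T alone or with T and then T or A, as the genomic sequence behind each of the 4 genes does, made a further class, trailer-type ends, which was added after the data were seen. In the first library, WT at 0 h replicate 1, the longest read had 58 nt. Each class was divided by all assigned reads of its library, with a minimum of 500 assigned reads. CCACCA, partial and longer CCACCA classes are given as RPM, reads in each 1000000 assigned reads of a library, and the other classes as percent. Single-library shares carry exact Clopper-Pearson 95% intervals, and a count of 0 was read as allowing up to 3 counts.

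Sequences were placed on the R64 reference genome by exact match, with the gene names of its annotation. The build the authors used is not given in the sources used here.

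Libraries were grouped by their titles. In 4 libraries the title and the hours tag disagree: WT at 3 h replicate 1 is tagged 1.5 h, and 3 U6:A67 libraries titled 6 h are tagged 0 h. The 4 trm8 trm4 libraries labelled 0.1 h carry 8 min in the names of their deposited files, and the labelled 0.1 h was kept. The series text states that biological replicates are included, and no label says which libraries came from which culture. Replicate libraries were checked for duplicates by a chi-square comparison of their end forms, and no pair of 1 group agreed within sampling noise.

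Groups, comparisons, end classes, tests, the rule for named forms and most alternatives were fixed before the data were examined. For 30 comparisons of the CCACCA share, two-sided permutation tests were used. Between strains the value is the mean, over shared time points, of the difference between group means, and strain labels were exchanged within time points. For a change with time the value is the last time point minus 0 h, and time labels were exchanged over all libraries of the strain. Where a strain had other time points, their libraries entered this exchange but not the value. The p value then rests on exchange among all times, not on the last time point and 0 h alone. For a difference between strains in their change with time, strain labels were exchanged within the first and last shared time point. All arrangements were enumerated up to 200000 (exact tests), otherwise 100000 were drawn, with a smallest possible p of 1e-05. Benjamini-Hochberg adjustment ran over 30 CCACCA tests, over 150 tests of the 5 other planned classes, and over 30 tests of trailer-type ends, at 0.05. Tests of trailer-type ends came after the data were seen.

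For 5 pairs of groups, every end form was tested. A count model had been planned for this, but the deposited unit is a count per read sequence rather than per feature, so limma 3.58.1 with an intensity trend was run on log2 RPM of assigned reads, with 0.5 reads added to each count and 1 to each library total. Forms with at least 10 reads in as many libraries as the smaller group holds were tested, with Benjamini-Hochberg adjustment. Named are the preset forms and, in each of the 5 scans, up to 10 forms with the largest change among those past the threshold with a mean of at least 10 reads, as the rule fixed beforehand states. Both kinds of test were tested on simulated data. With no simulated change, 3% to 7% of p values from the permutation tests lay below 0.05. At 10 RPM, a 2-fold change was recovered in 89% of simulations of trm44 tan1 against WT, 96% of trm44 tan1 met22 against trm44 tan1, 63% of xrn1 against WT and 63% of trm8 trm4 against WT, and a 4-fold change in 100%, 100%, 100% and 98%. Of 40 simulated changed forms, the scans recovered 0% of 2-fold and 0% of 4-fold changes for trm44 tan1 against WT at 3 h among 229 forms. For trm44 tan1 met22 against trm44 tan1 at 3 h they recovered 10% and 65% among 187 forms, and for trm44 tan1 xrn1 against trm44 tan1 at 3 h 0% and 5% among 247 forms. For trm44 tan1 at 6 h against 0 h they recovered 20% and 95% among 254 forms, with 2 false calls, and for trm8 trm4 against WT at 0.5 h 5% and 10% among 149 forms. Every simulated form of a scan had the median dispersion of its forms, 0.7227 for trm44 tan1 against WT at 3 h. The recovered shares therefore do not describe forms that vary less between libraries.

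Replicate numbers are shared between groups. In 11 of 54 pairs of groups, every pair of same-numbered libraries had end-form deviations with a correlation over 0.1, and 6 of 35 planned results rest only on such pairs of groups. These are the CCACCA comparisons of trm8 trm4 with WT, of their changes with time, of trm8 trm4 at 0.5 h with 0 h and of xrn1 at 6 h with 0 h, and the scans of trm44 tan1 against WT at 3 h and trm8 trm4 against WT at 0.5 h. The pairing comes from the correlations, not from a label, and it is loose. A library correlated best with its own number in 5 of 8 cases for trm44 tan1 and WT at 3 h. For trm8 trm4 and WT it did so in 4 of 8 at 0 h and 3 of 8 at 0.5 h. Within trm8 trm4 (0.5 h and 0 h) it was 5 of 8, and within xrn1 (6 h and 0 h) 4 of 6. Alternatives comprised a wider definition of CCACCA, another denominator, 1 mismatch in the body, a log2 scale, quasibinomial regression, a replicate block, other filters, and each library left out in turn. Added after the data were seen were median-of-ratios scaling, limma voom weights, and the leaving out of sets of libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3 were used.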

Results

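The 3′ ends of serine tRNAs were sequenced from yeast grown at 28 °C and moved to 37 °C, in 121 libraries from 10 strains. Most libraries read the endogenous tRNASer(CGA) together with tRNASer(UGA). The strains were WT, trm44 tan1, trm44 tan1 met22, trm44 tan1 xrn1, met22, xrn1 and trm8 trm4, all named as gene deletions. The other three strains were trm44 tan1 cells with an altered tRNASer(CGA), called U6:A67, G51:C63 and the triple variant (G51:C63 with C6:G67 and G2:C71). Trm44 methylates a ribose of serine tRNAs, Tan1 is needed to acetylate a cytidine, and Trm8 and Trm4 are tRNA base methyltransferases. Met22 is a phosphatase that removes pAp, an inhibitor of 5′-to-3′ exonucleases, and Xrn1 is one of these exonucleases. The CCA-adding enzyme gives each tRNA its 3′ CCA, and the series asks whether unstable tRNAs carry a second, appended CCA.

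WT was sampled at 0 h (n = 4), 0.5 h (n = 4), 1.5 h (n = 3), 3 h (n = 4) and 6 h (n = 3). The trm44 tan1 and trm44 tan1 met22 strains were each sampled at 0 h (n = 7), 1.5 h (n = 3), 3 h (n = 7) and 6 h (n = 6). The trm44 tan1 xrn1, met22 and xrn1 strains each had 3 libraries at 0, 3 and 6 h, and trm8 trm4 had 4 at 0, 0.1 and 0.5 h. Each variant had 3 libraries at 0 h and 3 at 6 h.

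Libraries held 29879 to 3635133 reads (median 2145677), of which 29422 to 3096577 (median 1748286) were assigned to the tRNA. The 103 libraries of endogenous tRNA had 107877 to 3096577 assigned reads. CCACCA ends were rare: 1612 reads in all libraries together, with 8 libraries at 0. The endogenous libraries held 1581 CCACCA reads, against 9999 of CCACC and 15846 of CCAC. Values are in RPM of assigned reads (reads in each 1000000 assigned) or in percent of assigned reads. They are means ± SD over the libraries of a group.

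The endogenous body sequence occurred 4 times in the R64 genome, each time in a tRNA gene. These were SUP61 (YNCC0013W, tRNASer(CGA), chromosome III, 227942 to 228042, body in exon 2 at 228023 to 228042) and the tRNASer(UGA) genes SUP16, SUP17 and SUP19. SUP16 (YNCP0012W) lies on chromosome XVI at 689565 to 689646 and SUP17 (YNCI0006W) on chromosome IX at 248850 to 248931. SUP19 (YNCE0015C) lies on the minus strand of chromosome V at 288443 to 288524.

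Whether serine tRNAs that lack both modifications carry CCACCA was asked by comparing trm44 tan1 with WT. In trm44 tan1, CCACCA ends rose from 4.72 ± 1.31 RPM at 0 h (n = 7) to 35.0 ± 8.57 at 6 h (n = 6), which is 7.41-fold. In WT they stood at 4.66 ± 3.19 RPM at 0 h (n = 4) and 7.12 ± 2.34 at 6 h (n = 3). At 6 h the trm44 tan1 libraries lay between 25.2 and 49.6 RPM and all 3 WT libraries at or below 9.81 RPM, a 4.92-fold difference of the means. At 3 h trm44 tan1 had 9.75 ± 3.94 RPM (n = 7) and WT 1.94 ± 0.573 (n = 4). Averaged over shared time points, trm44 tan1 was 9.51 RPM above WT (two-sided permutation test, p = 4e-05, adjusted p = 6e-04). The rise of 30.3 RPM in trm44 tan1 had p = 1e-05, the smallest the resampling can give, and adjusted p = 3e-04 in a two-sided permutation test. In WT the difference of 2.45 RPM did not pass (p = 0.20, adjusted p = 0.33, two-sided permutation test). The change with time was 27.8 RPM larger in trm44 tan1 than in WT (two-sided exact permutation test, p = 0.0062, adjusted p = 0.021). The call on this last difference was lost without WT 6 h replicate 3 (27.02 RPM), replicate 1 (27.25 RPM) or replicate 2 (29.16 RPM), and on a log2 scale (1.984).

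**Figure D1:**
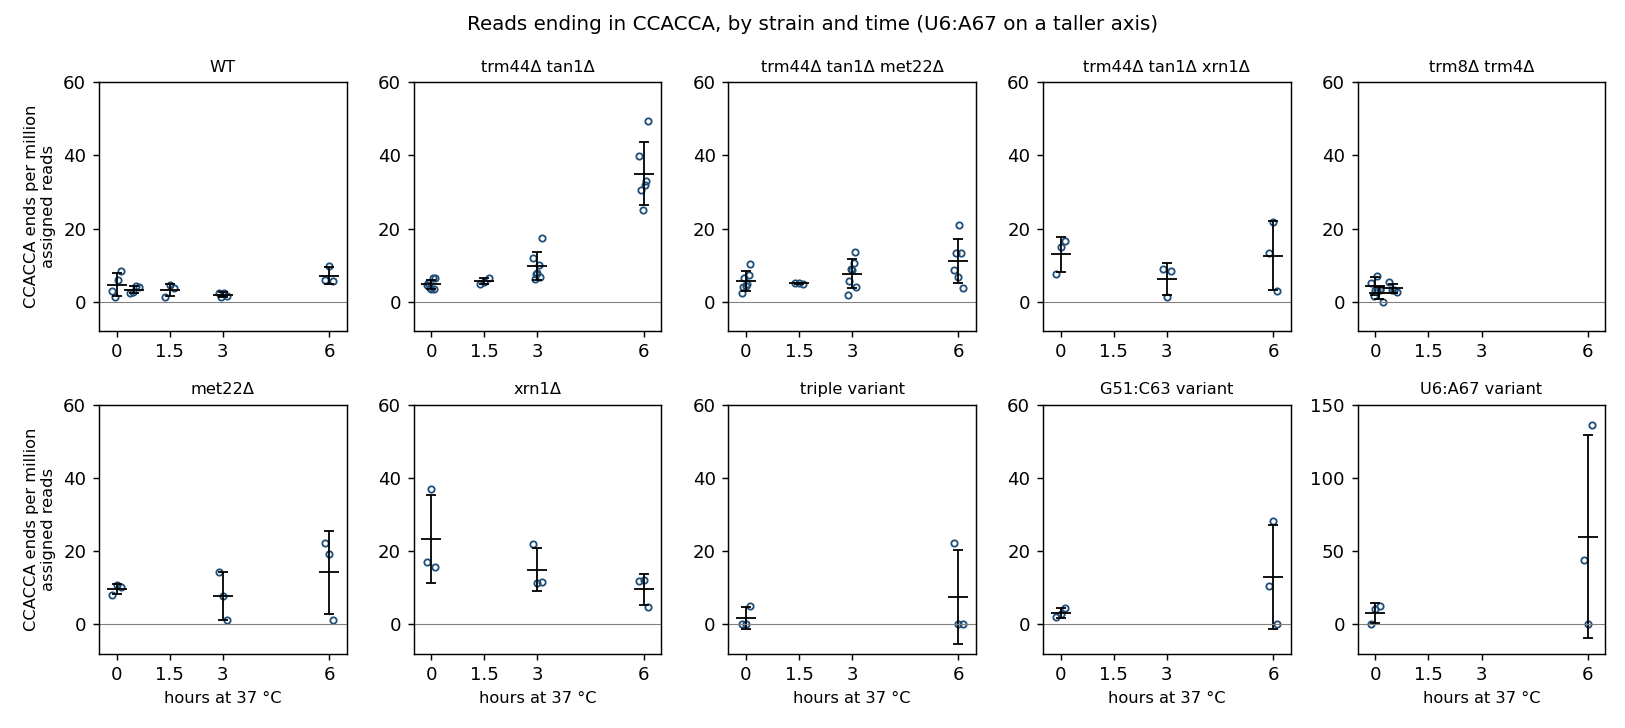
CCACCA ends in RPM of assigned reads against hours at 37 °C, 1 panel for each of the 10 strains; circles are libraries, short lines group means, bars SD. The trm44 tan1 libraries at 6 h lie at 25.2 to 49.6 RPM, above all WT libraries, and the U6:A67 panel has a taller axis.

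Ends with only part of a second CCA, CCAC and CCACC, were far more frequent than CCACCA and moved the same way in trm44 tan1. They rose from 47.4 ± 18.9 RPM at 0 h (n = 7) to 975 ± 306 at 6 h (n = 6), 20.6-fold, and in WT from 24.9 ± 17.4 (n = 4) to 74.2 ± 26.6 (n = 3), 2.99-fold. At 6 h all trm44 tan1 libraries held at least 724 RPM and WT libraries at most 101.5, and the means differed 13.2-fold. CCA followed by A only rose from 0.0832% ± 0.0284 to 0.846% ± 0.211 in trm44 tan1 and from 0.0268% ± 0.00867 to 0.0614% ± 0.00690 in WT. These A-extended ends were 13.8-fold higher in trm44 tan1 than in WT at 6 h. Over shared time points, trm44 tan1 exceeded WT by 330 RPM in partial second CCA ends and by 0.332 percent points in A-extended ends (two-sided permutation tests, adjusted p = 0.00015 for both). The rises with time in trm44 tan1 were 928 RPM and 0.763 percent points (adjusted p = 0.00015 for the first, two-sided permutation test), those in WT 49.3 RPM (adjusted p = 0.012) and 0.0347 percent points (adjusted p = 0.0044).

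**Figure D2:**
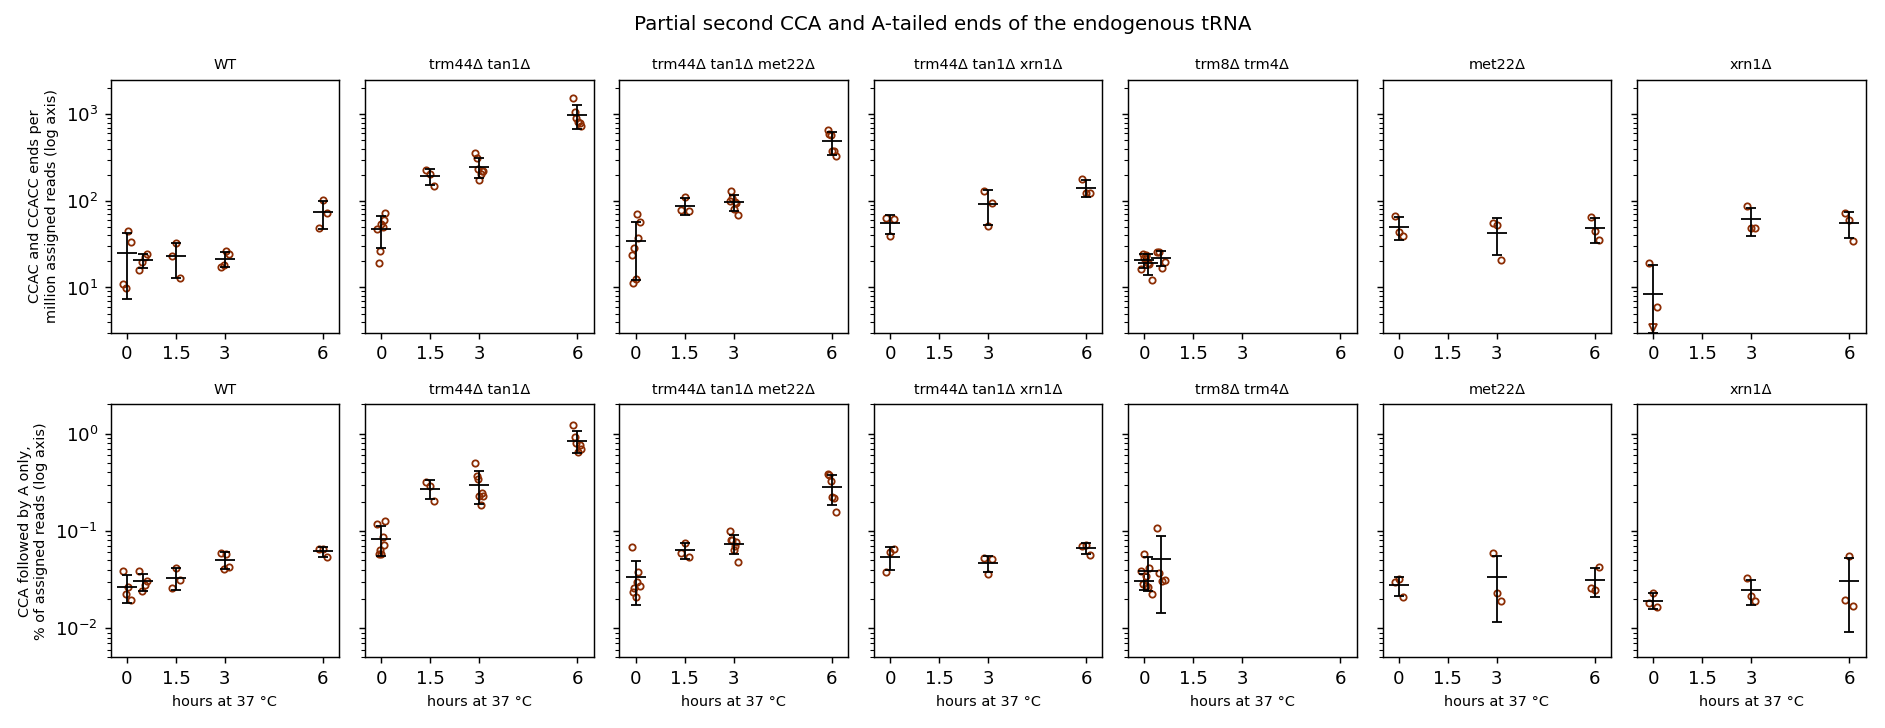
Partial second CCA ends (CCAC and CCACC, RPM, upper panels) and ends with CCA followed by A only (percent, lower panels) against hours at 37 °C on log axes for the 7 strains with endogenous tRNA; circles are libraries, lines means, bars SD, and an open triangle marks a library at 0. At 6 h the trm44 tan1 means are 975 RPM and 0.846%, against 74.2 RPM and 0.0614% in WT.

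Which single end forms changed over time in trm44 tan1 was asked with limma across all forms at 6 h (n = 6) against 0 h (n = 7). Of 254 forms, 54 rose and 153 fell. Among forms that begin with CCA, 33 of 56 rose and none fell, and among trailer-type forms, which begin with T and then T or A like the genomic sequence behind the 4 genes, 149 of 151 fell. CCACC rose by 6.27 ± 0.45 log2 (SE; 7.40 to 528 RPM, adjusted p = 3.2e-09), CCAC by 3.57 ± 0.32 (adjusted p = 2.3e-08) and CCACCA by 2.82 ± 0.35 (adjusted p = 7.5e-07). CCAA rose by 3.51 ± 0.25 log2 (379 to 4093 RPM, adjusted p = 3.2e-09) and CCAAAAAAAAAAA, with the longest A tail named, by 7.48 ± 0.66 (adjusted p = 1.8e-08). AAC rose from 1.32 to 188 RPM (7.40 ± 0.60 log2). The trailer-type form TTTAATTA, which begins like the sequence behind SUP61, fell by 6.95 ± 0.57 log2 and TTATTAA by 5.98. CC rose by 2.15 ± 0.30 log2, CCAG by 1.31 (adjusted p = 0.0065, not past the threshold without the filter on low counts), and CCA itself differed by 0.02 ± 0.12 (adjusted p = 0.87). With median-of-ratios scaling the median of all forms shifted by 2.22 log2, so that 107 forms rose and 109 fell, with 53 CCA-starting forms and 10 trailer-type forms higher and 108 trailer-type forms lower. Without the filter, 500 forms passed, 163 higher and 337 lower. C fell by 1.65 ± 0.30 log2 but had a positive value, 0.58, under that scaling.

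Against WT at 3 h (n = 4), trm44 tan1 (n = 7) had 88 of 229 forms higher and none lower in limma. CCACC was higher by 3.96 ± 0.54 log2 (SE; 81.5 ± 26.7 against 5.30 ± 2.55 RPM, adjusted p = 0.00043). CCAC was higher by 3.30 ± 0.44 (adjusted p = 0.00043), CCAAA by 3.45 ± 0.43 (948 ± 485 against 79.3 ± 13.3 RPM, adjusted p = 0.00042), CCAA by 2.04 ± 0.32 and CCAAAA by 2.73 ± 0.51. These 5 forms passed whichever library was left out. Without the filter on low counts, among 6706 forms, CCAAA alone of them passed, and with median-of-ratios scaling CCAA (0.3153) and CCAAAA (0.9985) did not. CCACCA was higher by 2.13 ± 0.59 (adjusted p = 0.016), a call lost without WT 3 h replicate 2 (2.00), replicate 4 (2.06) or replicate 3 (2.24), without the filter, and with median-of-ratios scaling (0.402). C (1.19, adjusted p = 0.057), CC (0.66, adjusted p = 0.11) and CCA (-0.10, adjusted p = 0.30) did not pass. Of trailer-type forms 68 of 108 were higher and of CCA-starting forms 15 of 72. The median-of-ratios scaling shifted the median by -1.73 log2 and gave 39 forms higher and 20 lower, with 32 trailer-type forms higher and 1 lower and 6 CCA-starting forms higher and 2 lower. With all libraries but WT 3 h replicate 2 the count was 31, and it was 32 without replicate 4, 34 without replicate 3, 133 without replicate 1, 132 with replicate numbers as a block, 28 without the filter and 134, with 14 lower, without the replicate 1 libraries of both strains. WT 3 h replicate 1, tagged 1.5 h, had 3.30% trailer-type ends against 0.112% to 0.149% in the other 3 libraries.

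Whether loss of Met22, which slows 5′-to-3′ decay, alters the extended ends was asked with trm44 tan1 met22. At 6 h (n = 6) this strain had 11.1 ± 6.08 RPM of CCACCA, 3.15-fold below trm44 tan1, with libraries between 3.81 and 21.0. Partial second CCA ends were 486 ± 143 RPM, 2.01-fold below trm44 tan1 and 6.55-fold above WT. A-extended ends stood at 0.281% ± 0.0948, 3.01-fold below trm44 tan1 and 4.58-fold above WT. Over shared time points trm44 tan1 met22 lay 6.41 RPM below trm44 tan1 in CCACCA (two-sided permutation test, p = 0.001, adjusted p = 0.0043), 190 RPM below it in partial second CCA and 0.262 percent points below it in A-extended ends (adjusted p = 0.00015 for both). The CCACCA change with time was 24.8 RPM smaller than in trm44 tan1 (two-sided permutation test, p = 0.00051, adjusted p = 0.0025).

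Compared with WT, trm44 tan1 met22 had 3.10 RPM more CCACCA (two-sided permutation test, p = 0.0099, adjusted p = 0.030). It had 140 RPM more partial second CCA (adjusted p = 0.00015) and 0.0700 percent points more A-extended ends (adjusted p = 0.0014). The CCACCA call was lost without WT 0 h replicate 2 (2.816), WT 6 h replicate 3 (2.905) or WT 6 h replicate 1 (2.96). Within trm44 tan1 met22, CCACCA at 6 h was 5.50 RPM above 0 h, which did not pass (two-sided permutation test, p = 0.022, adjusted p = 0.055). It passed without the libraries 3 h replicate 1 (5.496), 3 h replicate 6 (5.496), 6 h replicate 1 (5.98), 0 h replicate 7 (6.274), 6 h replicate 3 (6.378) or 6 h replicate 6 (6.959), and in a quasibinomial fit (log2 odds ratio 1.11). Partial second CCA ends rose by 451 RPM, 14.1-fold (adjusted p = 0.00015). The met22 strain, with its modification genes intact, had 14.2 ± 11.4 RPM of CCACCA at 6 h (n = 3) and lay 5.98 RPM above WT over shared time points, which did not pass (two-sided exact permutation test, p = 0.025, adjusted p = 0.058). That difference passed without WT 0 h replicate 4 (6.394), met22 3 h replicate 3 (7.065) or met22 6 h replicate 3 (8.158). Against met22, trm44 tan1 met22 differed by -2.44 RPM in CCACCA (adjusted p = 0.41, permutation test), and had 158 RPM more partial second CCA (adjusted p = 0.0059) and 0.0987 percent points more A-extended ends (adjusted p = 0.0015). The partial second CCA of met22 was 48.4 ± 15.6 RPM at 6 h, and that of trm44 tan1 met22 was 10.0-fold higher.

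In the limma scan of 187 forms at 3 h (n = 7 each), 10 forms were lower in trm44 tan1 met22 than in trm44 tan1 and none higher, 9 of them among 60 forms that begin with CCA. Among the 10 were CCAAA (-3.10 ± 0.35 log2, adjusted p = 2.9e-05), CCAAAAA (-2.49), CAAAA (-2.35), CCACC (-1.96 ± 0.37, adjusted p = 0.0027) and CCAA (-1.55 ± 0.22). These 5 forms and CCAAAA and CCAAC passed whichever library was left out, and of the 7 only CCAAA and CCAA passed without the filter on low counts. CCACCA had -0.49 ± 0.47 (adjusted p = 0.73). Median-of-ratios scaling shifted the median by 0.45 log2 and gave 21 forms higher and 22 lower, with all 9 CCA-starting forms it called lower. With replicate numbers as a block the count was 55, with 5 higher and 50 lower, and without the replicate 1 libraries of both strains it was 18, with 2 higher and 16 lower. Each of these 2 settings kept all 10 forms.

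Whether Xrn1 is involved was asked with trm44 tan1 xrn1 and xrn1. At 6 h (n = 3) trm44 tan1 xrn1 had 142 ± 31.2 RPM of partial second CCA, 6.89-fold below trm44 tan1 and 1.91-fold above WT. Its A-extended ends, at 0.0660% ± 0.00836, were 12.8-fold below those of trm44 tan1. Its CCACCA, 12.6 ± 9.49 RPM at 6 h, was 2.78-fold below that of trm44 tan1, and it was 13.0 ± 4.81 RPM at 0 h. The xrn1 strain had 23.3 ± 11.96 RPM of CCACCA at 0 h, 15.0 ± 5.99 at 3 h and 9.53 ± 4.24 at 6 h (n = 3 each).

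Over shared time points, trm44 tan1 xrn1 lay 327 RPM below trm44 tan1 in partial second CCA (adjusted p = 0.00068) and 0.354 percent points below it in A-extended ends (adjusted p = 0.00015; two-sided permutation tests). The CCACCA difference of -5.92 RPM did not pass (p = 0.10, adjusted p = 0.20, permutation test), while the change with time was 30.7 RPM smaller than in trm44 tan1 (two-sided exact permutation test, p = 9.9e-05, adjusted p = 0.00099). CCACCA exceeded WT by 11.4 RPM in xrn1 (two-sided exact permutation test, p = 0.00016, adjusted p = 0.0012). In 3 xrn1 libraries under 60% of reads were assigned, the lowest being 0 h replicate 2 with 22.5%, 107877 assigned reads and 37.1 RPM of CCACCA (95% Clopper-Pearson interval 10.1 to 94.9), and without these 3 libraries the difference was 9.835 RPM. When partial and longer forms were counted with CCACCA, the difference was 11.75 RPM and did not pass. CCACCA of trm44 tan1 xrn1 exceeded that of WT by 6.00 RPM (exact permutation test, p = 0.011, adjusted p = 0.031). This call was lost without any of 9 libraries: trm44 tan1 xrn1 6 h replicate 2 (4.468), 0 h replicate 3 (5.397), 3 h replicate 1 (5.537), 3 h replicate 3 (5.622), 0 h replicate 2 (5.685) and 6 h replicate 1 (5.897), and WT 0 h replicate 2 (5.616), 6 h replicate 3 (5.734) and 6 h replicate 1 (5.809). It was lost on a log2 scale as well (1.085).

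Against xrn1, trm44 tan1 xrn1 had 54.4 RPM more partial second CCA (adjusted p = 0.0059) and 0.0308 percent points more A-extended ends (adjusted p = 0.0019). Its CCACCA differed by -5.37 RPM (p = 0.15, adjusted p = 0.27; exact permutation tests). CCACCA at 6 h against 0 h differed by -13.8 RPM in xrn1 (p = 0.043, adjusted p = 0.092) and by -0.405 RPM in trm44 tan1 xrn1 (p = 0.95, adjusted p = 0.99; exact permutation tests), and the sign of the latter turned without 0 h replicate 2 (0.528), 0 h replicate 3 (1.393) or 6 h replicate 3 (4.48). In A-extended ends, xrn1 lay 0.0214 percent points below WT (adjusted p = 0.0053, exact permutation test). In the limma scan at 3 h (n = 3 against 7), 11 of 247 forms were lower in trm44 tan1 xrn1 than in trm44 tan1 and none higher, and 10 of them began with CCA. CCAAAAAAAA had -5.06 ± 0.75 log2 (adjusted p = 0.0011), CCAAAAAA -4.10, CCAAAAA -3.67, CCAAA -3.48 ± 0.48 (78.3 against 948 RPM) and CCAAAA -3.24, of which CCAAAAAAAA and CCAAA alone passed without the filter on low counts. CCACC (-1.60 ± 0.49, adjusted p = 0.092), CCAC (-1.48, adjusted p = 0.18) and CCACCA (-0.96 ± 0.70, adjusted p = 0.51) did not pass. The count was 7 without trm44 tan1 xrn1 3 h replicate 3 and 29, with 2 higher, without trm44 tan1 3 h replicate 1, and it was 4 without the filter. Median-of-ratios scaling shifted the median by 0.69 log2 and gave 9 higher and 16 lower, among them 10 CCA-starting forms, all lower.

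Strain trm8 trm4, known for the decay of a valine tRNA, was compared with WT to ask whether the ends of these serine tRNAs differ in a strain that keeps Trm44 and Tan1. At 0.5 h trm8 trm4 had 3.59 ± 1.14 RPM of CCACCA and WT 3.29 ± 0.958 (n = 4 each). At 0 h the values were 4.25 ± 2.35 and 4.66 ± 3.19 RPM. The difference over shared time points was -0.0547 RPM (p = 0.95, adjusted p = 0.99), that of 0.5 h against 0 h in trm8 trm4 was -0.657 RPM (p = 0.64, adjusted p = 0.74) and that between the changes 0.715 RPM (p = 0.73, adjusted p = 0.81; two-sided exact permutation tests). Leaving out single libraries moved the first value between -0.6245 and 0.5706 RPM, which turned its sign without trm8 trm4 0 h replicates 2 (0.382) and 4 (0.115), trm8 trm4 0.5 h replicates 2 (0.00281), 3 (0.0131) and 4 (0.0975), WT 0 h replicates 3 (0.171) and 4 (0.571) and WT 0.5 h replicates 3 (0.111) and 4 (0.0468). In the limma scan at 0.5 h, 0 of 149 forms passed, 3 had an unadjusted p under 0.05, voom weights gave 0 and median-of-ratios scaling 7. CCAAA had 1.13 ± 0.50 log2, with no adjusted p of a named form below 0.94.

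Whether base changes in the acceptor stem or T stem of tRNASer(CGA) alter its ends in trm44 tan1 was asked with the variants. U6:A67 had 405 ± 65.0 RPM of partial second CCA at 6 h and 17.6 ± 16.4 at 0 h. G51:C63 had 14.6 ± 4.03 RPM at 6 h and the triple variant 3.55 ± 6.14 (n = 3 each). A-extended ends at 6 h were 0.240% ± 0.0109 in U6:A67, 0.0413% ± 0.0414 in G51:C63 and 0.0141% ± 0.00322 in the triple variant, and 1 of the 3 G51:C63 libraries held 0.0890% and the other two at most 0.0197%. Over both time points, U6:A67 lay 0.123 percent points above G51:C63 and 0.141 above the triple variant in A-extended ends (two-sided exact permutation tests, adjusted p = 0.017 for both). U6:A67 was read with the endogenous primer and a filter for A67, G51:C63 and the triple variant with another primer. Effects of the variant and of the primer cannot be told apart, here or for CCACCA. The U6:A67 libraries at 6 h, grouped by title, are tagged 0 h.

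CCACCA rested on few reads in these strains: 8 in all U6:A67 libraries, 16 in G51:C63 and 7 in the triple variant. The 3 U6:A67 libraries at 6 h, grouped by title though tagged 0 h, had 2 reads (44.0 RPM, 95% Clopper-Pearson interval 5.33 to 159), 0 reads (which allows up to 83.1 RPM) and 4 reads (136 RPM, interval 37.0 to 348). Their mean was 59.98 ± 69.4 RPM, against 7.64 ± 6.73 at 0 h, a difference of 52.4 RPM. The differences of 6 h from 0 h were 9.81 RPM in G51:C63 and 5.71 RPM in the triple variant. With 3 libraries against 3, a two-sided exact permutation test has 20 arrangements and cannot go below p = 0.1, so none of these 3 changes with time could pass at any size (p = 0.40, 0.40 and 1). Between variants, U6:A67 differed from G51:C63 by 25.8 RPM (p = 0.21) and from the triple variant by 29.3 RPM (p = 0.15), and G51:C63 from the triple variant by 3.46 RPM (p = 0.49; exact permutation tests). Without U6:A67 6 h replicate 2 the first of these differences was 40.8 RPM and the second 44.26 RPM, and both passed. The sign of the third turned without G51:C63 6 h replicate 2 (-0.376) and that of the triple variant's change without its 6 h replicate 1 (-1.691). Against trm44 tan1 with endogenous tRNA, read with another primer in 2 of the variants, CCACCA was lower by 15.3 RPM in the triple variant (p = 0.0005, adjusted p = 0.0025) and by 11.9 RPM in G51:C63 (p = 0.006, adjusted p = 0.021; exact permutation tests), and U6:A67 differed by 14.0 RPM (p = 0.39). Those 2 calls were lost when only reads that hold the first CCA were the denominator (-13.38 and -6.648 RPM), and in a quasibinomial fit. The G51:C63 call was also lost without its 6 h replicate 1 (-11.24) or replicate 3 (-8.623), and for U6:A67 the value was 28.95 RPM and passed without 6 h replicate 2 and was -5.036 RPM without 6 h replicate 3.

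How unprocessed ends and ends short of CCA moved at 37 °C was asked across strains. Trailer-type ends fell in WT from 4.32% ± 2.04 at 0 h (n = 4) to 0.119% ± 0.0196 at 6 h (n = 3), 36.3-fold. In trm44 tan1 they fell 5.70-fold, from 7.65% ± 2.69 (n = 7) to 1.34% ± 0.407 (n = 6), which left them 11.3-fold above WT at 6 h. In trm44 tan1 met22 they fell 26.8-fold, to 0.150% ± 0.0470. The falls had adjusted p of 0.0056, 0.0017 and 0.0003, and those in met22 (39.9-fold) and trm44 tan1 xrn1 (14.0-fold) 0.0040 (two-sided permutation tests, chosen after the data were seen), and the fall in WT did not pass in a quasibinomial fit (log2 odds ratio -5.20). In xrn1 they fell 4.97-fold, from 4.69% ± 2.77 to 0.944% ± 0.435 (n = 3 each; difference -3.74 percent points, exact permutation test, adjusted p = 0.015), to a mean 7.93-fold above WT at 6 h, although over shared time points the difference of 0.817 percent points from WT did not pass (adjusted p = 0.30, exact permutation test). The fall in xrn1 lost its call without 6 h replicate 1 (-3.581), 2 (-3.653) or 3 (-3.988), without the 3 libraries with under 60% of reads assigned (-1.191) and in the quasibinomial fit (log2 odds ratio -1.629), and kept it at -2.272 without 0 h replicate 2. The tests of these falls also exchange the libraries of the times between, so their p values do not rest on 6 h and 0 h alone. In trm44 tan1 3 h replicate 1 trailer-type ends were 12.7%, against 1.35% to 2.88% in the other 6 libraries. Over shared time points trm44 tan1 lay 2.58 percent points above WT (adjusted p = 0.0013) and trm44 tan1 met22 2.28 percent points below trm44 tan1 (adjusted p = 0.0003). In the variants trailer-type ends took a large share, 75.6% ± 4.51 in the triple variant at 0 h, 66.7% ± 6.97 in G51:C63 and 39.5% ± 4.18 in U6:A67 (n = 3 each).

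**Figure D3:**
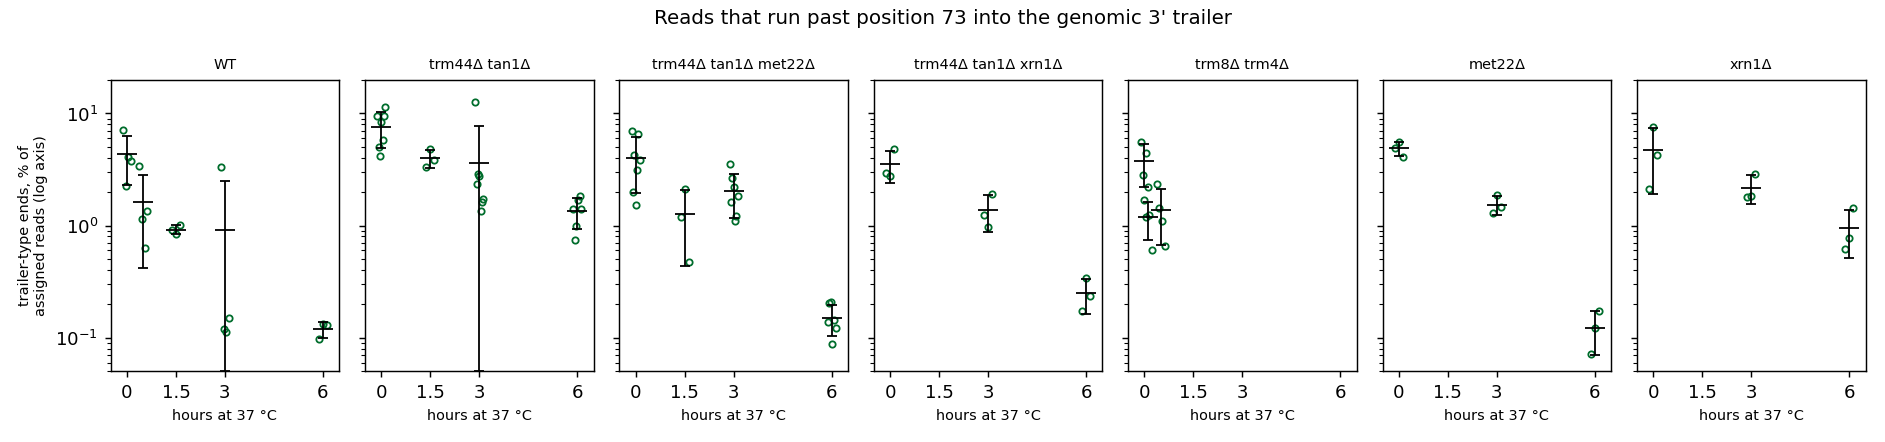
Trailer-type ends in percent of assigned reads on a log axis against hours at 37 °C for the 7 strains with endogenous tRNA; circles are libraries, lines means, bars SD, and the bars of WT and trm44 tan1 at 3 h end at the axis floor. The means at 6 h are 0.119% in WT, 1.34% in trm44 tan1 and 0.150% in trm44 tan1 met22.

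Ends short of CCA rose in WT from 4.57% ± 1.44 at 0 h to 16.3% ± 2.29 at 6 h, 3.57-fold (adjusted p = 0.0059, permutation test). At 3 h WT still had 3.61% ± 0.839 (n = 4). In trm44 tan1 the values were 10.1% ± 1.97 and 13.5% ± 7.37. The mean was also higher at 6 h in trm44 tan1 met22 (10.24% to 16.17%) and G51:C63 (10.26% to 12.67%). It was lower at 6 h in xrn1 (21.62% ± 10.51 to 4.463% ± 1.26) and trm44 tan1 xrn1 (13.13% ± 4.276 to 4.498% ± 1.926). The same held for met22 (11.53% to 8.246%), U6:A67 (13.8% to 6.262%) and the triple variant (5.907% to 3.293%). CC ends made up 12.1% ± 0.80 of WT reads at 6 h and 9.66% ± 5.76 of those of trm44 tan1. Among all 150 tests of the 5 other planned classes, 54 passed, and those of the variants at 6 h against 0 h could not, with 20 arrangements each.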

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

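The tests on trailer-type ends and on reads that end early were chosen after the data were seen, as were all tests in this part that weigh an explanation. In groups of 4 to 7 libraries, each library was compared with the others of its group, and 7 of 84 tests found a library apart, where chance alone gives about 4.2. CCACCA was 0 RPM in trm8 trm4 0.1 h replicate 4, which allows up to 1.76 RPM, against 3.20 to 3.36 in the other 3 libraries. A-extended ends stood apart in trm44 tan1 met22 0 h replicate 1 (0.0677% against 0.0209% to 0.0375%), trm8 trm4 0 h replicate 1 (0.0387% against 0.0265% to 0.0282%) and trm8 trm4 0.5 h replicate 1 (0.107% against 0.0304% to 0.0372%). CCACCA with further bases was 0.693 RPM in WT 3 h replicate 1 against 9.19 to 10.9. Trailer-type ends were 3.30% in WT 3 h replicate 1 against 0.112% to 0.149%, and 12.7% in trm44 tan1 3 h replicate 1 against 1.35% to 2.88%. Except for trm8 trm4 0.1 h replicate 4, every library apart was a replicate 1 library of a group at 0 to 3 h. The count expected by chance does not tell such a shared trait of libraries numbered 1 from single stray libraries.

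The high trailer-type share of WT 3 h replicate 1 was weighed against what its labels allow. In 9 other groups replicate 1 exceeded the rest by 1.281-fold to 6.003-fold, while here it did so by 26.08-fold, which argues against a 3 h library that differs only as other libraries numbered 1 do. The hours tag of this library reads 1.5, and it held 3.588 times the share of the WT 1.5 h libraries. That fold lies inside the range of those other groups only through trm44 tan1 3 h replicate 1 (6.003-fold), which itself stood apart. The next highest fold was 3.259 (WT 0.5 h), so whether a 1.5 h library numbered 1 accounts for the value could not be decided. Neither label says 0 h, and its share was 0.977 times that of the WT 0 h libraries not numbered 1, below the range of the other groups but inside the 2.25% to 7.12% of all WT 0 h libraries, so a wrongly labelled 0 h library cannot be told apart by this value. No biological explanation was tested, since the design gives none for a single library.

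The change from 0 h to the last time point differed between strains in 9 tests over 3 end classes. For CCACCA it was 27.8 RPM larger in trm44 tan1 than in WT (adjusted p = 0.021), and relative to trm44 tan1 it was -24.8 RPM in trm44 tan1 met22 (adjusted p = 0.0025) and -30.7 RPM in trm44 tan1 xrn1 (adjusted p = 0.00099, permutation tests). For a partial second CCA the differences were 879 RPM (adjusted p = 0.034), -477 RPM (adjusted p = 0.011) and -842 RPM (adjusted p = 0.013, permutation tests). For A-extended ends they were 0.729, -0.516 and -0.752 percent points (adjusted p = 0.035, 0.011 and 0.034, permutation tests). The CCACCA difference from WT lost its call without WT 6 h replicate 3 (27.02), replicate 1 (27.25) or replicate 2 (29.16). That of the partial second CCA lost it without trm44 tan1 6 h replicate 1 (763.8) or replicate 3 (894.9) or WT 6 h replicate 1 (865.9), replicate 3 (877.9) or replicate 2 (892.4). For A-extended ends it was lost without trm44 tan1 6 h replicate 1 (0.652) or replicate 3 (0.7372) or WT 6 h replicate 3 (0.7246), replicate 1 (0.7304) or replicate 2 (0.7307). The A-extended difference of trm44 tan1 xrn1 from trm44 tan1 was lost without trm44 tan1 6 h replicate 3 (-0.7601) or replicate 1 (-0.6749) or trm44 tan1 xrn1 6 h replicate 2 (-0.7543), replicate 1 (-0.7535) or replicate 3 (-0.7467). On a log2 scale, which compares folds, the calls for trm44 tan1 against WT were lost in CCACCA (1.984), partial second CCA (2.624) and A-extended ends (2.137), and those for trm44 tan1 met22 against trm44 tan1 in partial second CCA (-0.3927) and A-extended ends (-0.2665).

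Reads that end before position 67 were not assigned to an end class, and in 8 groups their share of all reads lay above that of every WT library of the same time. The mean was 1.51% in trm44 tan1 and 0.935% in trm44 tan1 met22 at 1.5 h, where WT had 0.490% (highest 0.531%). At 3 h it was 3.92% in trm44 tan1 xrn1 and 12.4% in xrn1, against 0.961% in WT (highest 1.29%). At 6 h it was 11.4% in trm44 tan1, 2.97% in trm44 tan1 xrn1 and 5.42% in xrn1, against 1.43% in WT (highest 1.66%). In xrn1 at 0 h it was 34.7% ± 32.6 (n = 3, from 7.55% to 70.9%), against 1.67% in WT (highest 3.82%).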

How the results depend on the processing

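Alternatives chosen after the data were seen were median-of-ratios scaling, voom weights and the leaving out of 2 sets of libraries: replicate 1 of the 10 groups at 0 to 3 h with at least 4 libraries, in each of which it had the lowest share of CCA with other added bases, and xrn1 libraries with under 60% of reads assigned. The planned TMM scaling and a second count tool were not run, as the scans used limma, and a minimum of 5000 assigned reads removed 0 libraries. Leaving out the 4 libraries with disagreeing labels left U6:A67 without a 6 h library and kept all 9 CCACCA results it could reach. Where a value below changed sign or call, the cause was not tested. Depth limits CCACCA most in the variants, where a count of 0 allows 24.24 and 83.11 RPM in the 2 U6:A67 libraries that had none. CCACCA of trm44 tan1 against WT (8.782 to 9.999 RPM) and at 6 h against 0 h (27.35 to 32.22), of trm44 tan1 met22 against trm44 tan1 (-6.901 to -5.681), of xrn1 against WT (9.064 to 12.62) and the change with time of trm44 tan1 xrn1 against trm44 tan1 (-35.25 to -25.78) kept their calls whichever library was left out.

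Of 30 CCACCA results, 17 kept direction and side of the threshold when partial and longer forms were counted as well, 28 with reads holding the first CCA as denominator, 27 with 1 mismatch, 26 on a log2 scale, 26 in the quasibinomial fit and 19 with a replicate block. With partial and longer forms the values in RPM were 11.75 (xrn1 against WT, no longer past the threshold), -336.1 (trm44 tan1 xrn1 against trm44 tan1, now past it), 62.78 (WT 6 h against 0 h, now past it), 476.7 (trm44 tan1 met22 6 h against 0 h, now past it), 226.7 and 225.8 (U6:A67 against G51:C63 and the triple variant, now past it). They changed sign for trm44 tan1 met22 against met22 (161.1), trm44 tan1 xrn1 against xrn1 (50.44), trm44 tan1 xrn1 (82.37) and xrn1 (36.79) at 6 h against 0 h, trm8 trm4 at 0.5 h against 0 h (0.1641), G51:C63 against the triple variant (-0.8535) and U6:A67 against trm44 tan1 (-302.3).

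With reads holding the first CCA as denominator, G51:C63 (-6.648) and the triple variant (-13.38) against trm44 tan1 no longer passed, and CCA with other added bases of the triple variant against trm44 tan1 turned from -0.183 to 0.01908 percent points. With 1 mismatch the sign turned for CCACCA at 6 h against 0 h in trm44 tan1 xrn1 (0.4792) and the triple variant (-0.9745) and for G51:C63 against the triple variant (-0.5743). Ends short of CCA then turned for U6:A67 and G51:C63 against the triple variant (from 5.43 and 6.87 to -12.69 and -5.745 percent points) and for the triple variant against trm44 tan1 (from -7.15 to 10.98). On a log2 scale trm44 tan1 xrn1 against WT (1.085) and the change with time of trm44 tan1 against WT (1.984) no longer passed, and trm8 trm4 against WT (0.06597) and met22 at 6 h against 0 h (-0.2431) changed sign. In the quasibinomial fit (log2 odds ratios) trm8 trm4 against WT changed sign (0.1009), trm44 tan1 met22 at 6 h against 0 h passed (1.11), and G51:C63 (-1.045) and the triple variant (-1.426) against trm44 tan1 did not.

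In the 6 results whose same-numbered libraries all correlated, a replicate block left the 4 CCACCA results on their side of the threshold and the scan of trm8 trm4 against WT at 0. It moved the scan of trm44 tan1 against WT from 88 to 132 forms, 84 of them shared. In other results it leaves out any libraries without a partner and allows fewer arrangements, and these no longer passed: trm44 tan1 (8.294), trm44 tan1 met22 (2.032), trm44 tan1 xrn1 (6.375) and xrn1 (11.74) against WT, trm44 tan1 met22 (-6.409), G51:C63 (-10.18) and the triple variant (-13.64) against trm44 tan1, trm44 tan1 at 6 h against 0 h (30.53), and the changes with time of trm44 tan1 against WT (25.2) and of trm44 tan1 met22 (-24.76) and trm44 tan1 xrn1 (-27.83) against trm44 tan1. Between trm44 tan1 met22 and trm44 tan1 every library had a partner, so left-out libraries do not account for the calls lost there. With the block 7 other-class tests passed in place of 54, 6 of them shared. Left out one at a time, single libraries kept 520 of 567 CCACCA values, 1087 of 1155 values of called other-class results and 640 of 684 of named forms.

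Single libraries left out gave ranges of 2.609 to 3.467 (trm44 tan1 met22 against WT), 4.468 to 7.624 (trm44 tan1 xrn1 against WT), 4.65 to 8.158 (met22 against WT), -0.6245 to 0.5706 (trm8 trm4 against WT), 24.9 to 29.76 (change with time, trm44 tan1 against WT), -0.5351 to 1.855 (change with time, trm8 trm4 against WT), -5.036 to 28.95 (U6:A67 against trm44 tan1) and -15.68 to -8.623 (G51:C63 against trm44 tan1). For the last time point against 0 h they were 3.529 to 6.959 in trm44 tan1 met22, -4.991 to 4.48 in trm44 tan1 xrn1, -1.53 to 0.2894 in trm8 trm4 and -1.691 to 9.409 in the triple variant. Between variants they were 10.27 to 44.26 (U6:A67 against triple), 6.814 to 40.8 (U6:A67 against G51:C63) and -0.3763 to 7.157 (G51:C63 against triple). Of these, the sign in trm8 trm4 at 0.5 h against 0 h turned without 0 h replicate 3 (0.2894) and that of its change with time against WT without WT 0 h replicate 4 (-0.5351) or trm8 trm4 0 h replicate 2 (-0.158).

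The scan counts moved by more than 1.5 times in these cases. For trm44 tan1 at 3 h against WT (88) they were 28 with no filter on low counts, 134 without the replicate 1 set, and 31 to 133 without single libraries. For trm44 tan1 met22 against trm44 tan1 (10) they were 55 with a replicate block, 18 without the replicate 1 set and 43 with median-of-ratios scaling, which shifts all forms of a library alike. For trm44 tan1 xrn1 against trm44 tan1 (11) they were 4 with no filter, 29 without the replicate 1 set, 25 with median-of-ratios scaling and 7 to 29 without single libraries. For trm44 tan1 at 6 h against 0 h (207) the count was 500 with no filter, and C turned from -1.65 to 0.5765 log2 with median-of-ratios scaling. For trm8 trm4 against WT at 0.5 h (0 in limma, 3 at an unadjusted p under 0.05, 0 with voom) it was 7 with median-of-ratios scaling, a median shift of 0.16 log2. Without the replicate 1 set, 19 of 20 CCACCA results were kept and trm44 tan1 xrn1 against WT (5.862) no longer passed. Without the xrn1 libraries all 3 CCACCA results were kept, and 3 of 7 other-class calls and the trailer-type call were lost.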

Other observations

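All tests in this part were chosen after the results they measure had been seen. Reads that end before position 67, of which 14.3% at 0 h and 16.6% at 6 h held the primer alone, rose in trm44 tan1 from 3.65% ± 1.27 of all reads at 0 h (n = 7) to 11.4% ± 3.15 at 6 h (n = 6; p = 0.00016, adjusted p = 0.00024 over 6 permutation tests), 7.98-fold above WT at 6 h. In trm44 tan1 met22 they were 1.98% at 6 h, and over shared time points the strain lay 3.13 percent points below trm44 tan1 (difference -3.13, adjusted p = 3e-05, permutation test). In trm44 tan1 xrn1 the means were 4.45% at 0 h, 3.92% at 3 h and 2.97% at 6 h, above the 3.65% and 2.66% of trm44 tan1 at 0 h and 3 h and below its 11.4% at 6 h. Averaged over these times the difference of -2.12 percent points did not pass (adjusted p = 0.086, permutation test), but passed without trm44 tan1 xrn1 3 h replicate 2 (-2.363). The xrn1 strain exceeded WT by 16.2 percent points (exact permutation test, adjusted p = 8.2e-05), and by 10.13 without xrn1 0 h replicate 2, which alone held 70.9%. In xrn1 the shares were 34.7% ± 32.6 at 0 h and 5.42% ± 3.38 at 6 h (n = 3 each), a difference of -29.3 percent points (exact permutation test, adjusted p = 0.041). The 3 h libraries enter this test but not the difference, so its p does not rest on 6 h and 0 h alone. The call on this difference was lost without 7 of the 9 xrn1 libraries: 0 h replicates 2 (-11.22) and 3 (-33.8), 3 h replicates 1 and 2 (-29.31 for both) and 6 h replicates 1 (-27.96), 2 (-28.76) and 3 (-31.2).

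Trailer-type ends could be told apart by gene where the read went far enough into the genomic sequence. In trm44 tan1 at 6 h the ends of SUP61, SUP16, SUP17 and SUP19 were 13.5-fold to 16.6-fold above WT, and in trm44 tan1 met22 12.8-fold to 15.4-fold below trm44 tan1. All 8 of these comparisons passed over shared time points (permutation tests, highest adjusted p = 0.011). From 0 h to 6 h they fell 30.7-fold (SUP16) to 114.5-fold (SUP61) in WT and 3.36-fold (SUP16) to 12.2-fold (SUP19) in trm44 tan1. These folds count only reads that went far enough, a share that differed between groups and so enters the folds. At 6 h, 83.9% ± 1.49 of trailer-type reads in trm44 tan1 had at least 6 bases past position 73, against 55.2% ± 7.99 in trm44 tan1 met22 and 60.4% ± 1.76 in WT. A leucine tRNA (YNCG0028W, chromosome VII, 700675 to 700756) was amplified with the variants' primer and took 20.3% ± 8.12 of reads of the triple variant at 0 h and 73.4% ± 5.26 at 6 h, and 9.48% ± 2.21 and 40.9% ± 30.6 in G51:C63 (n = 3 each). Other serine tRNA genes took 0.610% ± 0.499 of reads in trm44 tan1 at 6 h (n = 6) and 0.118% in WT.

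In trm44 tan1 at 6 h, CCACC outnumbered CCACCA 15.7 ± 5.93 times (n = 6), and in WT 3.05 ± 0.333 times (n = 3). Reads too short to show CCACCA are argued against, as at least 81.9% of trailer-type reads in each of the 6 libraries reach as far. Loss of the last base from any CCA in library making is argued against, since CCACC per CCACCA was at least 7.02 where CC per CCA was at most 0.2575. Trimming that needs Xrn1 could not be decided: the ratio differed by -5.81 in trm44 tan1 xrn1, with exact p = 0.31 over 84 arrangements, while trm44 tan1 met22, in which 5′-to-3′ decay is slowed, had a mean of 24.1 ± 15.1 (n = 6). A slow last step of the second CCA addition, or its removal by another nuclease, may account for the ratio and was not tested.

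Reads with a partial second CCA had more mismatches at position 58, where serine tRNAs carry a methylated A, than CCA reads: 22.65% against 9.94% in trm44 tan1 at 6 h, a difference of 12.7 ± 2.56 percent points (higher in 6 of 6 libraries). An exact sign-flip test of this difference gave p = 0.031, the smallest 6 libraries allow, and adjusted p = 0.044 over 24 tests. At other positions the mean difference was 0.0075 percent points, which argues against more errors along the whole read. At 0 h the difference was -0.03 ± 3.46 percent points, and 6 h exceeded 0 h by 12.74 (exact permutation test, p = 0.00058). The added bases differed between these times. CCAC stood at 39.96 RPM and CCACC at 7.40 RPM at 0 h, against 447 RPM and 528 RPM at 6 h. The contrast of times therefore cannot decide whether the added bases themselves cause misreading. In trm44 tan1 met22 at 0 h the difference was 3.67 ± 3.31 percent points, higher in 5 of 6 libraries. A partial second CCA placed more often on tRNA with methylated A58 is a hypothesis left open by these values. The sign-flip test cannot tell it from other causes of mismatches at this position. A-extended reads of trm44 tan1 showed 6.98 ± 1.77 percent points more mismatches than CCA reads there at 6 h, and 4.05 ± 1.29 more at 0 h. Among CCA reads, 2 libraries of trm44 tan1 met22, 0 h replicate 4 (0.209%) and 1.5 h replicate 3 (0.105%), had almost no mismatch at position 58 against 6.17% to 19.9% in 101 others.

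In 4 of the 5 scans, other splits of the same libraries rarely or never gave as many forms as the real grouping. Counts of splits below include the real one. For trm44 tan1 at 3 h against WT, 2 of 100 splits gave as many forms as the real 88, and the highest other, 110, exchanged WT replicate 1 with trm44 tan1 replicate 7. Same-numbered libraries of these groups correlated, though only 5 of 8 libraries correlated best with their own number. The 4 other splits drawn that part every same-numbered pair gave at most 0. These are too few to exclude chance with such a pairing kept. For trm44 tan1 met22 against trm44 tan1, 1 of 100 splits reached 10 and the highest other was 0. For trm44 tan1 xrn1 against trm44 tan1, 2 of 100 splits reached 11, the highest other being 14, and for trm44 tan1 at 6 h against 0 h 1 of 100 reached 207, the highest other being 173. For trm8 trm4 against WT at 0.5 h the real count and the highest other were 0, which all 35 splits reach whatever the data, so the splits say nothing about this scan.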
